A study of Oryza sativa Japonica Group with 8 samples.

How the data were processed

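PolyA RNA was measured. It had been extracted from dissected rice pistils with a micro-scale column kit, per the labels' protocols. For the upper and lower parts, libraries were made from whole-cell RNA with a strand-specific kit (NEBNext Ultra II Directional). For the nuclei, ground tissue was suspended in isolation buffer, strained, and purified by PI-labelled FANS, a fluorescence-based sorting, before RNA extraction and library preparation with a SMART-Seq kit, per the labels' protocols. Kit and compartment therefore coincide. The submitters' processing notes name STAR (a read aligner), featureCounts (a read counter), DESeq2 and the genome build IRGSP-1.0, without versions. Whether counting used strand, and how reads matching several places were treated, is not given in the sources used here.

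The authors deposited 1 table of counts, whole numbers per feature and library, with no normalization. It has 38726 features: 37849 loci with RAP identifiers, 755 with ENSRNA identifiers, 11 with EPlORYSAT identifiers and 111 organelle genes given by name. All 8 columns were matched to samples by name, and 0 columns of per-sample values were left unused. The series also covers single-nucleus libraries, which were not analysed here. No genome sequence was used. The gene name table of the reference assembly ASM3414082v1 matched only 1 RAP identifier, so nuclear loci have no names here and its coordinates were not used; chromosome numbers were read from the locus identifiers. That table, built on another assembly than the counts, was used to assign organelle genes: 46 names occur in the mitochondrial genome alone, 45 in the plastid genome alone, 17 in both and 3 in neither.

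Differential expression was tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test on counts with TMM scaling and edgeR's filter on low counts. Benjamini-Hochberg adjustment ran over all genes tested, and a call needed an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Upper and lower libraries were compared in a fit of those 6 libraries. Nuclei were set against the mean of the parts on the log2 scale in a fit of all 8. For nuclei outside both parts, the larger of the one-sided p-values against each part was adjusted over genes and directions, with a log2 fold change of at least 1 against each part. CPM values were computed from the deposited counts with TMM-scaled library sizes for single genes (over the 6 whole-cell libraries for upper against lower, over all 8 otherwise), and with total counts for summed classes. Fold changes against a group with no counts are lower bounds against a floor of 3 counts over that group, from pooled counts over total counts. With 1 to 3 counts, and for rpoC2 with 4, the ratio of pooled counts with its exact 95% interval is given. Repeating bounds and ratios with a library left out, and counting non-overlapping genes in other splits, was added after the data were seen. Intervals and floors cover counting error alone, since the labels name no molecular identifiers. Shares of counts per library were compared by exact permutation tests, and between the parts also by exact permutation within replicate pairs, all chosen after the data were seen. In a single library, with TMM scaling over all 8, 3 counts correspond to 0.0754 to 0.1355 CPM in the whole-cell libraries and to 0.273 and 0.377 CPM in nuclei.

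The fits were tested on simulated counts with 50 genes changed at each fold. For upper against lower (29848 genes) 0, 7, 28 and 44 of the 50 genes were recovered at 2-, 4-, 8- and 16-fold, with 10 false calls. With the replicate block 3, 33, 45 and 49 were recovered, with 15 false calls. For nuclei against the parts (31858 genes) 0, 7, 30 and 41 were recovered, with 6 false calls. Read against the genes recovered, the false calls in each fit exceeded the share that an adjusted p under 0.05 aims at. Without the block, most of the simulated changes of 4-fold or less were thus missed. The simulated counts held no deviation shared by replicate pairs. They also had a far smaller share of changed genes than the 22.9% called between nuclei and parts. The numbers with the block and for nuclei may therefore not carry over to the data.

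Replicate numbers come from the labels. Whether they pair the upper and lower libraries was checked by the correlation, across genes, of the deviations from the group means. It was 0.332, 0.636 and 0.622 for replicates 1, 2 and 3, the highest value for unlike numbers was 0.0618, and all 6 libraries correlated best with their own number. By mean correlation the labelled matching ranked 1 of 6, with 0.530 against at most 0.0977 for another. Deviations from a group mean cancel out, so the 6 best matches are not independent. The 6 matchings are also too few for a share under 0.05. On these values the numbers were taken as pairs, and results with the replicate number as a block are given beside the main ones. What the pairs share (a day, plants or a library batch) is not stated in the labels.

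The following choices were made before the data were examined: the grouping, the tests of genes and gene lists, the alternatives unless stated otherwise, the gene lists and the rule for named genes. Among genes called, with non-overlapping libraries (for nuclei, every nuclei library above or below all 6 whole-cell libraries), a mean of at least 10 CPM in the higher group and a name, the rule takes the 8 with the largest absolute fold in each direction, plus up to 2 in each direction from each list with at least 3 called members or a camera call. Members of the lists of floral MADS-box genes and YABBY genes were also to be named, but none could be matched. The rule gave 8 organelle genes, rpoC2, rpoB, orfB, rps1, ccmFn, orf165, rps4 and ndhF. The other organelle genes in the text were chosen after their values were seen, as were their groups by function. Since nuclear loci have no names here, at most 2 locus identifiers per direction and comparison are printed, by the same rule without the name. None of these 7 loci had a neighbour with nearly equal counts.

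Of the 28 gene lists, 25 had 0 matched members. They covered floral, cell wall, hormone, defence, sugar, cell cycle, meiosis, pollen, stress, aquaporin, splicing and chromatin genes, and no result is given for them. The photosynthesis list had 3 tested members, all plastid-encoded, and the list of plastid- and mitochondrion-encoded genes 27. A list of cytosolic ribosomal proteins matched organelle ribosomal genes alone and was left out. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01 and with an estimated one. 1 list was tested, so no adjustment over lists was needed.

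In 1018 pairs of loci with neighbouring identifiers, whole-cell counts differed by under 5% (over at least 100 counts). The authors' counting may have assigned the same reads to overlapping or copied loci there, and 27 of the 242 genes higher in the upper part are in such a pair. Results were repeated with other scalings (RLE, library size only), other filters (none beyond 1 count, at least 5 CPM in 2 libraries), counts thinned to the smallest library, a replicate block, DESeq2 1.42.0, no fold threshold, a test against a 2-fold change, all 8 libraries in 1 fit, either part alone as the reference, and each library left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.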

Results

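Gene-level read counts were obtained from pistils of rice (Oryza sativa ssp. japonica, cultivar Nipponbare), sampled at heading. The pistil is the female organ of the flower and carries the stigma and style above the ovary. It had been separated into an upper and a lower part, and the labels do not state where it was divided. There were 8 libraries in 3 groups: whole-cell RNA of the upper part (n = 3), whole-cell RNA of the lower part (n = 3) and RNA of sorted nuclei from pistils (n = 2). Total counts were 27217580, 34767439 and 26983741 in upper replicates 1, 2 and 3 and 24796307, 35518142 and 24962880 in lower replicates 1, 2 and 3. The nuclei libraries were shallower, with 10857036 and 9268151 counts. Of the 38726 features in the count table, 1690 had no count in any library. No 2 libraries were alike: at least 85.4% of the features had different counts in any pair of libraries. The labels do not say whether the replicates came from separate plants, so p-values measure the spread between these samples, which may be technical.

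**Figure D1:**
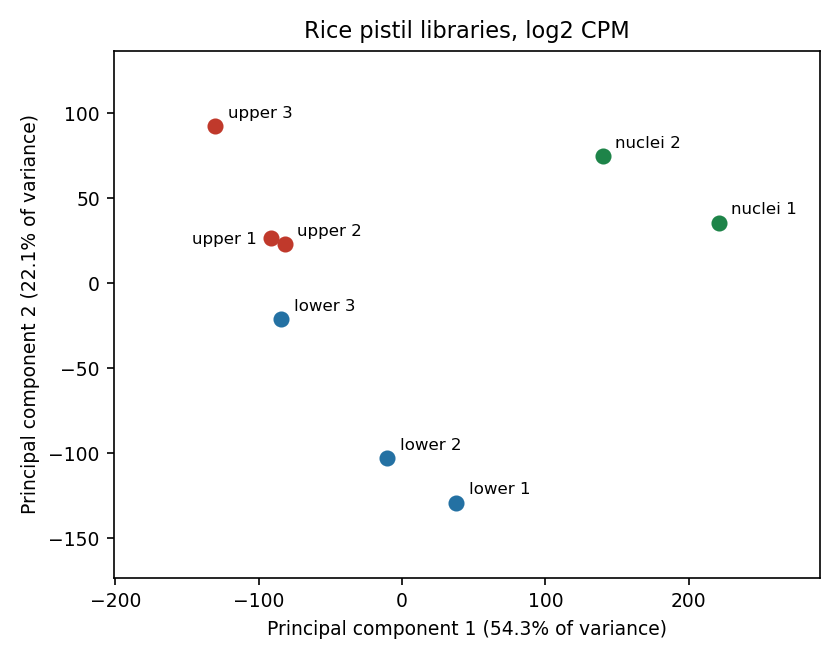
Principal components of log2 CPM (counts scaled to a common library size) over 24619 genes, 1 point per library, coloured by group (red upper, blue lower, green nuclei). The first component, with 54.3% of the variance, sets the nuclei libraries apart from the whole-cell libraries, and on the second, with 22.1%, lower replicate 3 lies between the upper libraries and the other lower libraries.

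The first comparison asked which transcripts differed between the upper and the lower part of the pistil. Without a block for the replicate number, 242 of 29848 genes tested were called higher in the upper part and 1 was called lower (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The median log2 fold change of the 242 genes was 4.18, also with the 4 genes that had no count in the lower part set to their lower bound. The range was from 1.45 to 9.33 among genes with a count in the lower part, 131 of the 242 were at least 16-fold higher, and 73 had a mean under 1 CPM in the lower part. Most were well expressed in the upper part, where 209 had a mean of at least 10 CPM and 59 a mean of at least 100 CPM. In all 242 genes every upper library lay above every lower library. Across all genes tested, 3067 had all upper libraries above all lower libraries and 3064 the opposite, which is 20.5% of the genes. Chance gives 10% for 6 exchangeable libraries, which pairs that deviate together are not. The 3 other splits that part all replicate pairs gave 1.91%, 2.04% and 2.89%, whereas 2 splits that keep 2 of the 3 pairs together gave a higher share than the real one, up to 28.0%, so this share alone does not set the real split apart.

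The reference table names only 1 of the 37849 nuclear loci in the count table, so single nuclear genes are given by locus identifier. Among genes called with at least 10 CPM in the higher part, the locus with the largest fold was Os02g0801255 on chromosome 2. It had 41.8, 9.12 and 17.5 CPM in the upper libraries and 0.0301 ± 0.0325 CPM in the lower part (SD, n = 3), with a log2 fold change of 9.33 (SE 0.97, Benjamini-Hochberg adjusted p = 0.0109, edgeR quasi-likelihood test). The lower libraries held 3 counts of this locus in all, and the ratio of the pooled counts was 561, with a 95% counting interval from 192 to 2722. That ratio was 311 (106 to 1513) without upper replicate 1 and 1193 (214 to 47149) without lower replicate 1. Next was Os04g0332700 on chromosome 4, with 263, 2845 and 784 CPM in the upper libraries and 3.58 ± 2.23 CPM in the lower part (SD, n = 3). Its log2 fold change was 8.50 (SE 1.24, edgeR adjusted p = 0.0362). This locus had 0 counts in both nuclei libraries, which allows at most 0.273 and 0.377 CPM there. The single locus called lower in the upper part, Os01g0533000 on chromosome 1, had 6.76 ± 1.21 CPM in the upper and 27.5 ± 6.46 CPM in the lower part (SD, n = 3 each). Its log2 fold change was -2.02 (SE 0.32, edgeR adjusted p = 0.0414).

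Upper and lower libraries were taken as pairs by replicate number (the check and its limits are given with the processing). With the replicate number as a block 1529 genes were called higher and 902 lower in the upper part. All 242 genes called higher and the 1 called lower without the block were called in the same direction with it. In every gene called with the block, all 3 pairs went the same way. The blocked count depended on single pairs: without pair 1, 2 or 3 there were 2284, 98 and 2289 genes higher and 1265, 0 and 644 lower. For the 0 without pair 2, edgeR gave 2603 genes lower at an unadjusted p under 0.05. The gains with the block were also larger than the losses: 261 genes were at least 16-fold higher in the upper part and 3 at least 16-fold lower. The median log2 fold changes were 2.11 and -1.51, also with the 10 genes that had no count in the lower part at their bound. With library size as the only scaling, the blocked split turned to 1294 higher and 2993 lower, because that scaling moved the median log2 fold change of all genes to -0.34. With the scaling used for the main result that median was -0.02.

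**Figure D2:**
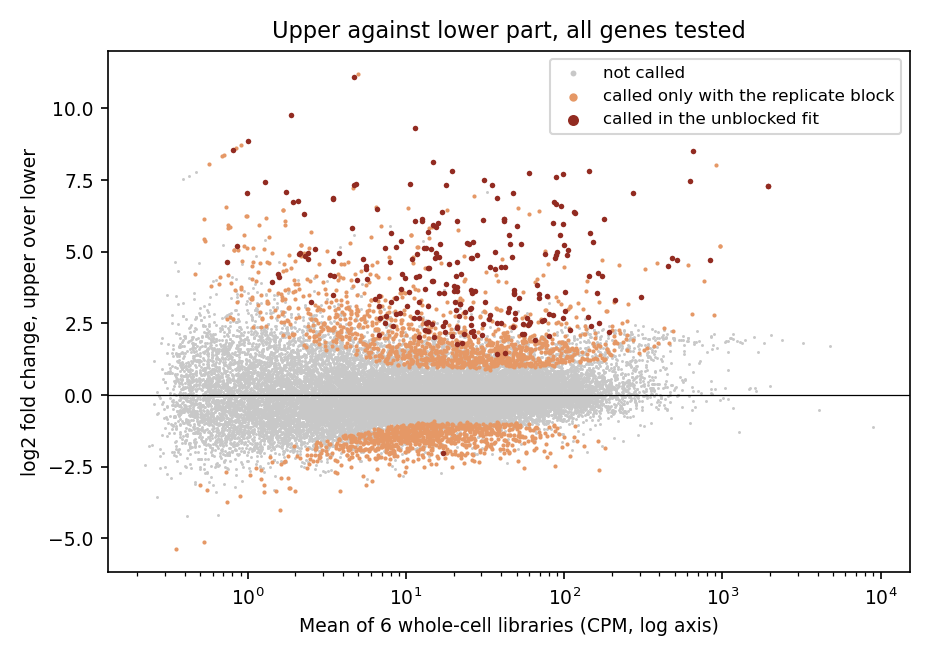
Log2 fold change of the upper over the lower part against the mean CPM of the 6 whole-cell libraries (log axis), 1 point per gene tested. Dark red points are the 243 genes called without the block, orange points those called with the replicate block alone, and grey points genes not called; the largest changes in size lie above 0, toward the upper part.

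The number of calls between the parts depended on single libraries, and lower replicate 3 stood apart from its group. Its mean Spearman correlation across genes was 0.929 with the 3 upper libraries and 0.897 with the other 2 lower libraries, and no other whole-cell library was closer to the other part than to its own. Without lower replicate 3, 916 genes were called higher and 42 lower in the upper part, and 237 of the 242 genes remained among them. Without upper replicate 1, 2 or 3 the calls were 105, 110 and 58 higher and 5, 0 and 0 lower; for the zeros, edgeR gave 1830 and 693 genes lower at an unadjusted p under 0.05. Without lower replicate 2 they were 49 higher and 0 lower, with 1644 lower at an unadjusted p under 0.05. Without lower replicate 1 edgeR called 0 genes in either direction, with 1589 higher and 842 lower at an unadjusted p under 0.05, while DESeq2 called 853 higher and 85 lower. Os02g0801255 lost its call without lower replicate 1 or 2 (edgeR adjusted p = 0.0588 and 0.0617; from 3.24e-16 with DESeq2 to 0.0617 over all alternatives), and its log2 fold change was 8.56 without upper replicate 1 and 10.18 without lower replicate 1. Os04g0332700 lost its call without upper replicate 3, lower replicate 1 or lower replicate 2 (edgeR adjusted p = 0.0857, 0.186 and 0.149; from 9.23e-24 with DESeq2 to 0.186 over all alternatives). In these fits its log2 fold change was 8.77, 8.32 and 8.18. The call was also lost when tested against a 2-fold change (edgeR adjusted p = 0.0537). Its log2 fold change was 7.19 without upper replicate 2, 9.09 without lower replicate 3, 7.91 with the block, and 6.80 with the block and pair 2 left out. Os01g0533000 kept its call only without lower replicate 3 among the libraries left out, and its adjusted p ran from 1.52e-05 with DESeq2 to 0.186 with edgeR over all alternatives. Where leaving out a library lost the call, the log2 fold change was between -1.84 and -2.17. The call was also lost with the block and pair 2 left out, and when tested against a 2-fold change (edgeR adjusted p = 0.0807 and 0.154).

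The second comparison set the nuclei against the mean of the whole-cell parts. Of 31858 genes tested, 4502 were called higher in nuclei and 2791 lower, together 22.9% of the genes. By the fitted fold, 880 genes were at least 16-fold higher and 888 at least 16-fold lower. With folds against a group with no count set to their bound the numbers were 880 and 797, and by pooled counts with the same floor 727 and 822. Of the genes called higher, 119 had no count in any of the 6 whole-cell libraries, and of those called lower, 194 had no count in either nuclei library. Os01g0791033 on chromosome 1 had 132 and 732 counts in the nuclei libraries and 0 counts in the whole-cell libraries, at least 2494-fold higher against a floor of 3 counts over the whole-cell group (edgeR adjusted p = 0.00109). Os10g0356000 on chromosome 10 had 5.37 and 40.7 CPM in nuclei and 0 whole-cell counts, at least 1105-fold higher (edgeR adjusted p = 0.00158). Both bounds rest mostly on nuclei replicate 2: without it they were 706-fold and 316-fold, and without nuclei replicate 1 they were 4587-fold and 2030-fold. Summed counts of organelle genes were also higher in nuclei replicate 2 than in nuclei replicate 1 (1122 against 146.8 CPM). Whether the counts at both loci came from organelle-derived reads was not tested, so they may not be transcripts of nuclear genes. In the opposite direction, Os11g0696600 and Os11g0686100 on chromosome 11 had 83.8 ± 32.2 and 86.1 ± 48.7 CPM in the whole-cell libraries (SD, n = 6) and 0 counts in nuclei. They were at least 576-fold and 568-fold lower in nuclei (edgeR adjusted p = 0.000246 and 0.000424), and the bounds were 265-fold and 261-fold without nuclei replicate 1 and 310-fold and 306-fold without nuclei replicate 2. Nuclei and whole-cell libraries were also made with different kits, so compartment and kit cannot be told apart in any of these differences. Other differences between these samples were not tested as a source. Whether called loci lie next to each other was tested between the upper and lower parts alone. The number of calls depended on the method: 5108 higher and 4394 lower with the replicate block, and 5375 and 4331 with DESeq2. Against the lower part alone it was 3230 and 1719, and tested against a 2-fold change 2179 and 845. Without nuclei replicate 1 the calls fell to 1970 higher and 408 lower.

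Most plastid- and mitochondrion-encoded genes that could be tested had higher counts in nuclei. PolyA RNA was measured, so these counts may not follow the level of all organelle RNA in either kind of library. The filter kept 39 of the 111 organelle genes, and 33 of them were called higher in nuclei. None was called lower by edgeR, none had an unadjusted p under 0.05 in that direction, and DESeq2 called 33 higher and 0 lower. The sum over all 111 organelle genes, which does not depend on the filter, was 146.8 and 1122 CPM in nuclei replicates 1 and 2, against 7.90 ± 3.73 CPM in the whole-cell libraries (SD, n = 6). Every nuclei library was above every whole-cell library (exact permutation test, two-sided, p = 0.0357, the smallest that 28 splits allow; Benjamini-Hochberg adjusted p = 0.0476 over 4 library measures). The nuclei replicates differed from each other by more than the whole-cell libraries did, so the size of each fold is uncertain. Of the 27 tested members of the organelle gene list fixed beforehand, 22 were called higher, and 24 when adjusted over the list alone. These counts rest on genes that mostly passed the filter through their counts in nuclei: only 3 of the 27 list members, and 4 of the 39 genes, also passed it in the whole-cell libraries alone. Of those 3 members edgeR and DESeq2 called 0 higher, with 1 at an unadjusted p under 0.05, and of the 4 genes cob was called. Without a filter 67 of 104 organelle genes were called higher and 0 lower, with 0 lower at an unadjusted p under 0.05. The camera test of the 27 list members gave p = 2.96e-15 with the preset correlation and p = 0.0931 with an estimated correlation, so the list's call was lost with the latter. As most members passed the filter through their counts in nuclei, the filter favours this direction in both settings.

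By pooled counts, with a floor of 3 counts over the whole-cell group, the organelle genes with the largest ratios were rpoC2 and rpoB. rpoC2, which encodes a subunit of the plastid-encoded RNA polymerase, had 32.7 and 313 CPM in the nuclei libraries and 0.0203 ± 0.0388 CPM in the whole-cell libraries (SD, n = 6), with an edgeR adjusted p of 0.000323. It had 2848 counts in nuclei, 0 in the upper part and 4 in the lower part. It was at least 4197-fold higher than in the upper part, and its ratio to the lower part was 3017 (95% counting interval from 1177 to 11080). rpoB, another subunit, had 4.92 and 51.9 CPM in nuclei and 0 whole-cell counts, at least 1348-fold higher (edgeR adjusted p = 0.00189). The groups that follow were formed from the gene names after the data were seen. All 3 tested polymerase genes were called higher, with rpoA at a log2 fold change of 6.35 (SE 1.10). Among ribosomal protein genes 9 of 11 were called higher, among them rps1 (log2 fold change 9.34, SE 0.85) and rps4 (7.77, SE 0.79). rps1 reached 16.9 and 222 CPM in nuclei and rps4 12.7 and 72.0 CPM. All 3 tested genes for cytochrome c maturation were called higher, led by ccmFn (8.54, SE 0.75), with 17.6 and 157 CPM in nuclei against 0.229 ± 0.119 CPM in whole cells (SD, n = 6). All 5 tested genes of the plastid NDH complex, which takes part in electron transport around photosystem I, were called higher, among them ndhF (7.60, SE 1.03). The 3 tested genes with ATP synthase (atp) names, atp1, atp6 and atpI, were called higher as well. So were all 8 tested genes named as open reading frames (orf), whatever their function, with orf165 at a log2 fold change of 8.21 (SE 0.87). orfB, also listed as an open reading frame, had 1.37 and 26.6 CPM in nuclei and 0 whole-cell counts, at least 655-fold higher. The edgeR adjusted p-values of rps1, rps4, ccmFn, ndhF, orf165 and orfB lay between 0.000246 and 0.00412. The sizes depended on single libraries, while all 8 genes named by rule kept their call where they were tested. Without nuclei replicate 2 the log2 fold changes of rps1, ccmFn, orf165, rps4 and ndhF were 6.49, 6.23, 5.95, 6.03 and 5.33, and without nuclei replicate 1 they were 10.23, 9.38, 9.06, 8.53 and 8.45. The log2 fold change of rps4 was 8.37 without upper replicate 2 and that of ndhF 9.38 without upper replicate 3. The bounds of rpoB and orfB were 289-fold and 80.2-fold without nuclei replicate 2, and 2588-fold and 1329-fold without nuclei replicate 1. For rpoC2 the bound against the upper part was 981-fold without nuclei replicate 2, 7964-fold without nuclei replicate 1 and 2557-fold without upper replicate 2. Its ratio to the lower part was 705 without nuclei replicate 2, 5725 without nuclei replicate 1, and 8559 (1535 to 3.38e+05) without lower replicate 1, where 1 count is left.

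**Figure D3:**
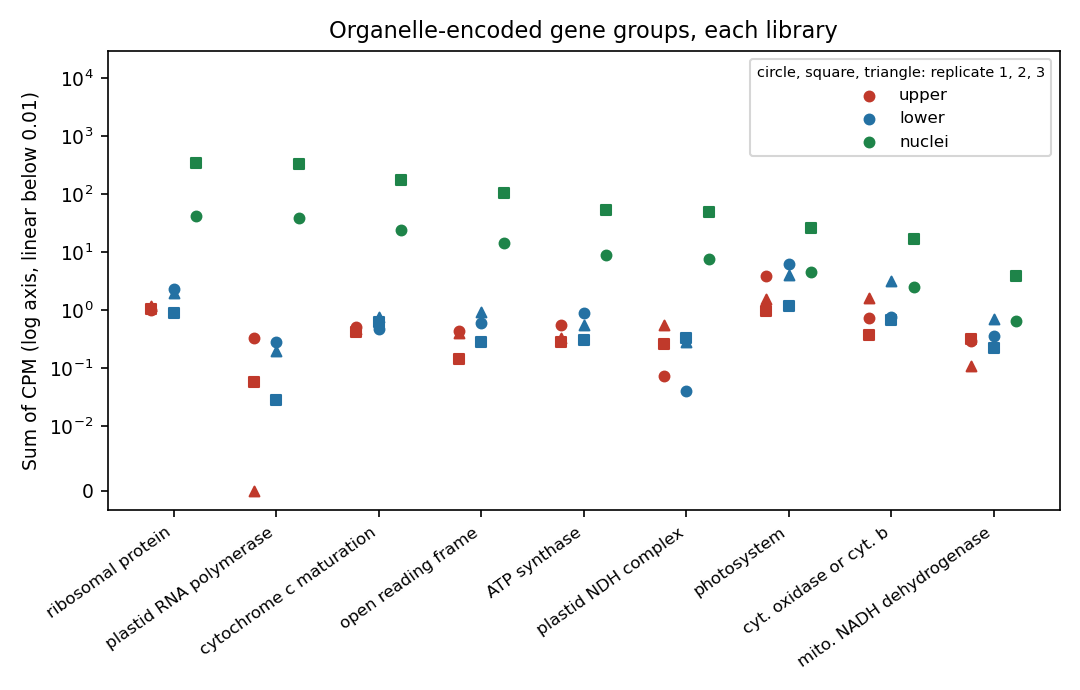
Summed CPM of organelle gene groups (log axis, linear below 0.01) in each of the 8 libraries, red upper, blue lower and green nuclei, with marker shape giving the replicate. In the ribosomal protein group the nuclei libraries hold 42.9 and 347 CPM against a whole-cell mean of 1.42 CPM, whereas in the photosystem, cytochrome oxidase and mitochondrial NADH dehydrogenase groups nuclei replicate 1 lies within the whole-cell range.

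Among organelle genes for the photosystems and the respiratory chain, few could be tested. Of the 3 tested members of the photosynthesis list, all plastid-encoded, psbB was called higher (log2 fold change 4.39, SE 0.79, edgeR adjusted p = 0.00508), and 1 member passed when adjusted over the list alone. psbK had a log2 fold change of 2.79 (SE 1.20, edgeR adjusted p = 0.117). psaC, a photosystem I subunit, had 2.63 ± 2.68 CPM in nuclei (SD, n = 2) and 2.16 ± 1.41 CPM in whole cells (SD, n = 6), with a log2 fold change of 0.29 (SE 0.88, edgeR adjusted p = 0.831). For the mitochondrial respiratory chain, cob was called higher (log2 fold change 3.74, SE 0.90, edgeR adjusted p = 0.0174). cox2 and nad4L were not called, with log2 fold changes of 1.46 (SE 0.94) and 0.72 (SE 1.18). The remaining genes not called were rps16 and rps7-3, with log2 fold changes of 3.74 (SE 1.43) and 3.52 (SE 1.19). Between the upper and lower parts 4 organelle genes could be tested. edgeR and DESeq2 called 0 of them, and 0 had an unadjusted p under 0.05, at 3.91 to 12.7 summed CPM per library. The sum over all organelle genes was higher in the lower part in 3 of 3 replicate pairs (exact permutation test within pairs, two-sided, p = 0.25, the smallest that 3 pairs allow; Benjamini-Hochberg adjusted p = 0.333 over 4 measures).

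Features other than named loci were also set side by side. Features with ENSRNA identifiers made up 0.0758 ± 0.0237% of the counts in nuclei (SD, n = 2) and 0.0415 ± 0.0195% in whole cells (SD, n = 6), a difference within the permutation spread (exact permutation test, two-sided, p = 0.107; Benjamini-Hochberg adjusted p = 0.107 over 4 measures). Of the 223 tested, 33 were called higher in nuclei and 24 lower. Of the 11 features with EPlORYSAT identifiers 6 could be tested, and all 6 were called higher in nuclei. They summed to 35.1 and 164 CPM in the nuclei libraries and to 1.04 ± 0.58 CPM in whole cells (SD, n = 6; exact permutation test, two-sided, p = 0.0357, Benjamini-Hochberg adjusted p = 0.0476). Between the upper and lower parts the ENSRNA share was higher in the lower part in 3 of 3 replicate pairs, and the EPlORYSAT sum in 2 of 3. Exact permutation tests within pairs, two-sided, gave p = 0.25 and 0.75 (Benjamini-Hochberg adjusted p = 0.333 and 0.75 over 4 measures), where 3 pairs cannot give less than 0.25. Exact permutation tests without pairing, two-sided, gave p = 0.2 and 0.6 (adjusted p = 0.4 and 0.6), where 3 libraries against 3 cannot give less than 0.1.

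The third comparison asked which genes in nuclei lay outside the range of both whole-cell parts, since the nuclei came from pistils and not from 1 part. There were 1390 genes above both parts and 646 below both. All of these were also among the genes called against the mean of the parts. With library size as the only scaling the split was 1234 above and 1051 below, and with the replicate number as a block it was 2091 above and 1644 below. The number of genes depended on single libraries: without upper replicates 1, 2 or 3 it was 583, 939 and 737 above and 293, 413 and 365 below. Without lower replicates 1, 2 or 3 it was 995, 795 and 927 above and 1172, 479 and 427 below. Without nuclei replicate 1 it was 414 above and 134 below.

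The place of the nuclei libraries between the parts depended on the measure. Positions were computed on log2 CPM, with the mean of the lower part at 0 and that of the upper part at 1. Over the 243 genes called between the parts, the median position was 0.53 for nuclei replicate 1 and 0.87 for nuclei replicate 2. The middle 50% of these positions ranged from 0.24 to 0.78 and from 0.55 to 1.09. In log2 CPM, 47.7% and 20.2% of the 243 genes lay nearer to the lower part. For genes higher in the upper part, as 242 of the 243 were, an equal mixture of the parts lies above the midpoint of this scale. These positions are therefore not shares of tissue. The order turned with another measure: the linear mixture share of the upper part, fitted on CPM over all genes, was 0.107 for nuclei replicate 1 and -0.42 for nuclei replicate 2. Over all genes tested, the Spearman correlation of nuclei replicate 1 was 0.709 with the mean of the upper part and 0.781 with the mean of the lower part, and that of nuclei replicate 2 was 0.787 and 0.813. These are correlations across genes, which are not independent replicates.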

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

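The tests that left out a replicate pair, reduced loci that share reads, combined the block with another scaling, filtered on the whole-cell libraries alone or used upper-quartile scaling were chosen after seeing the data. For genes higher in the upper part, 9 of 24 alternatives stayed within 1.5 times the 242 calls. With the replicate block there were 1529 higher and 902 lower, with DESeq2 1296 and 397 (6033 adjusted p-values were NA), and tested against a 2-fold change 95 and 0 (394 lower at an unadjusted p under 0.05). Leaving out 1 library gave 0 to 916 higher and 0 to 42 lower. With the block and pair 1, 2 or 3 left out there were 2284, 98 and 2289 higher and 1265, 0 and 644 lower (for the 0, 2603 at an unadjusted p under 0.05). The block with library size only gave 1294 and 2993, with RLE 1762 and 1083, and with loci that share reads reduced to 1 gave 1484 and 884. The single gene lower became 3 with library size only or all 8 libraries in the fit, and 2 with either other filter or upper-quartile scaling (median of all genes -0.13). For nuclei against the parts, a test against a 2-fold change gave 2179 higher and 845 lower, and leaving out 1 library 1970 to 4246 and 408 to 3191. Genes lower in nuclei numbered 4394 with the replicate block, 4331 with DESeq2 and 1719 against the lower part alone. With library size only the median log2 fold change of all genes was -0.17, against -0.03. Where 1 nuclei library was left, it was assumed to vary like the other groups. Genes outside both parts became 2091 above and 1644 below with the block, 1051 below with library size only, and 414 to 1027 above and 134 to 1172 below with 1 library left out. Nuclei share 2 replicate numbers with the parts, and their deviations correlated from -0.00904 to 0.347 with those of the same number, so these samples were not treated as paired. Organelle list members higher in nuclei rose from 22 to 45 without a filter and fell to 4 at 5 CPM in 2 libraries, since more or fewer were tested; among the 3 members that pass the filter on the whole-cell libraries alone it was 0 (1 at an unadjusted p under 0.05, 0 with DESeq2). The camera p rose to 0.0931 with an estimated correlation, and the block changed no call of a named gene or list. The linear mixture share of the upper part was 0.107 and -0.42 for nuclei replicates 1 and 2, which turns their order, and the latter lies outside the range a mixture allows. For the other changes the cause was not tested. Among named genes, 157 of 157 values for organelle genes and 80 of 80 for loci in nuclei kept direction and call. rpoB, orfB and ndhF did not pass the filter of 5 CPM in 2 libraries and have no value there. Dropping the fold threshold reuses the main p-values, so it could not lose a call. For the loci named between the parts 72 of 72 kept direction and 13 lost the call. Few organelle genes could be tested between the parts, as the whole-cell libraries hold 136 to 317 such counts each.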

Other observations

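The tests given here were chosen after the results were seen, except the question of the kit and the projection of the upper-lower direction, whose division by replicate was also made afterwards. Genes that differed between the parts lay next to each other on the chromosomes more often than in random sets. With 1 locus kept of each run that shares reads, among 228 loci higher in the upper part without the block there were 31 adjacent pairs, where 10000 random sets matched on expression gave 1.82 ± 1.34 (SD over sets; permutation p = 0.0001, the smallest they can give). With the block there were 307 adjacent pairs among 1454 higher loci against 73.6 ± 8.32, and 146 among 876 lower loci against 27.8 ± 5.04 (permutation p = 0.0001 each). A run of 4 neighbouring loci on chromosome 5 had a median log2 fold change of 4.34, with means of 169.9 CPM in the upper and 8.93 CPM in the lower part. A run of 3 on chromosome 11 had a median of 6.31, with 109.8 and 0.641 CPM. The longest run with the block had 6 loci, on chromosome 10, higher in the upper part with a median log2 fold change of 5.77. Only neighbours whose counts differed by under 5% had been reduced. Whether the runs are gene copies, or loci that share part of their reads, was not tested. By chromosome, called loci were not distributed beyond chance after adjustment: the smallest of 12 Benjamini-Hochberg values (Fisher's exact test) was 0.521 for loci higher without the block, and 0.929 and 0.254 for loci higher and lower with it.

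Nuclei libraries held counts at loci with none in whole cells. With all libraries thinned to 9268151 counts, 3911 features had no count in any whole-cell library. Nuclei replicates 1 and 2 had counts at 1270 and 1586 of them, and 952 had counts in both. A single whole-cell library had counts at 130 to 352 of the features with none in the other 5. Thinned nuclei libraries detected 32483 and 34141 features against 31848 ± 489 in whole cells (SD, n = 6; exact permutation test, two-sided, p = 0.0357, the smallest that 28 splits allow; Benjamini-Hochberg adjusted p = 0.0476 over 4 measures).

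Chance as the source of the upper-lower calls was examined with the 10 splits of the 6 whole-cell libraries into 3 and 3. The real split gave 243 calls and the highest of the others 0, and only the real split (1 of 10) gave as many; 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the other splits gave 61 to 6001 genes and the real one 4144, and the highest came from upper replicates 1 and 3 with lower replicate 3 against the rest. The 3 other splits that part all replicate pairs gave 0 calls also with the block, where the real split gave 2431.

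Lower replicate 3 resembled the upper libraries. Exchanged labels are argued against by the 200 strongest upper genes found without it, over those genes alone. Its median position over them was 0.0463 on a scale from 0 (lower) to 1 (upper), where the upper libraries had medians from 0.481 to 1.11. Over the 200 strongest lower genes it stood at 0.626, nearer the upper end than upper replicate 1 at 0.536. The lower genes therefore do not argue against an exchange with that library. After thinning, its mean correlation with the upper libraries still exceeded that with the other lower libraries by 0.0417. Random thinning is not expected to change this, so it is no test of depth. Lower replicate 1 had a similar total (24796307 against 24962880 counts) but was closer to its own part, with mean correlations of 0.914 against 0.829. An even admixture of upper tissue would set each upper gene at the same share of its upper level, but over the 916 genes called higher without it 35.3% stood at 10% or less and 31.6% at 75% or more, and its quartile ratio was 7.42 times that of the most variable upper library. A candidate explanation that stays open is a different place of division, which may bring in tissue near the boundary; the labels do not give it and it was not tested.

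Upper and lower libraries with the same replicate number deviated together. The lowest of the 3 correlations was 0.332 before thinning and 0.333 after it. Random thinning is not expected to remove differences in scaled levels, so this is no test of depth. Total counts were highest in replicate 2 of both parts, so depth and what goes with it stay open. A shift along the upper-lower direction alone is argued against for replicates 2 and 3, whose correlations with that direction projected out were 0.621 and 0.413, above the highest value for unlike numbers, 0.302. For replicate 1 it was 0.187, below that value, so this stays open; the bound of 0.1 set beforehand was too low, since unlike numbers exceed it. A shared day, plant batch or library batch remains open as a candidate source and was not tested.

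Counts of organelle-encoded genes were higher in nuclei, although the nuclei had been sorted. After thinning, the lower nuclei library had 10.3 times the organelle CPM of the highest whole-cell library. Random thinning is not expected to change a share of counts, so this outcome was fixed beforehand and is no test of depth. A larger amount of the same organelle RNA was examined by whether the gains were even. Over the 15 genes with at least 20 whole-cell counts the log2 fold changes ran from 0.29 to 9.34. Their interquartile range was 3.72 times that of the ratio between the nuclei libraries (3.56 times by the fitted values of all 39 genes tested). The nuclei libraries share a kit while the fold changes cross kits, so kit effects that differ by gene could also make the gains unequal. The unequal gains therefore cannot decide this. The library kit stays open, because 0 nuclei libraries were made with the whole-cell kit, and kit and compartment cannot be told apart. Organelle RNA or DNA held on sorted nuclei may also contribute and was not tested.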
